A study of Mus musculus with 6 samples.

How the data were processed

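RNA from 6 cultures of primary mouse dermal fibroblasts, 3 without and 3 with 100 nM synthetic Et1 for 24 hours, was hybridised to Affymetrix Mouse430_2 arrays. Per the labels, total RNA was extracted with a commercial kit and labelled with biotin by in vitro transcription. The deposited values are linear intensity signals per probe set, made with MAS5 per the submitters' processing notes; its version and scaling are not given in the sources used here. The deposited experiment files hold settings as text, with 1 distinct text over the 6 files once the lines for sample type, project and operator were left out.

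The deposited intensity signals were not at a common level: the 2% trimmed means ran from 91.7 to 179, so each array was scaled to their geometric mean of 139. The 4 zero values were set to the smallest positive value of their array, and log2 was taken with no pseudocount. The table held 45101 probe sets, 64 of them Affymetrix controls, which were left out. A probe set was tested where its mean scaled signal over the 6 arrays was at or above the median of 41.0, which left 22519 of 45037. Affymetrix signals carry no count of molecules, so the precision of a comparison was taken from the number of arrays and the spread between them. A fold change of a probe set near the filter is sensitive to background, and fold changes are on the log2 scale without a pseudocount.

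Probe sets were named from the platform annotation. Of 45037 probe sets, 34945 had 1 gene symbol, 932 several and 9160 none, and no gene was named from a probe set with several. Of the single symbols, 34754 were found by their gene identifier in a table of mouse genes (assembly GRCm38.p6), and 0 had to be changed. No coordinates were used. Genes of the lists with no single-symbol probe set in that annotation were not analysed here.

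Groups and replicate numbers came from the labels. The labels call the arrays biological replicates, and nothing in them names the animals. The p-values per probe set therefore measure the spread between these arrays. With no block, that spread includes the difference between the spike-in sets described below. Each probe set was compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, no block), with Benjamini-Hochberg adjustment over the 22519 probe sets and a threshold of 0.05. For the gene lists each gene was represented by its brightest tested probe set, 11666 genes in all, and lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry, which tests whether a list moves one way on balance, were alternatives. At the preset correlation camera compares the genes of a list with all other genes, so its p-values do not measure the spread between cultures. The lists covered the endothelin system, immediate-early factors, MAPK and G-protein feedback, collagens, other matrix genes, contractile genes, the TGF-beta response, proteases, cytokines, interferon-stimulated genes, growth factors, the S phase, the G2 and M phases, growth control, cholesterol synthesis, the unfolded protein and amino acid stress response, hypoxia and glycolysis, the dermal fibroblast lineage, and markers of 10 other cell types.

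Genes named in the text followed a rule written with the lists: the 10 largest rises and the 10 largest falls past the threshold with no overlap between the groups, each gene by its probe set with the smallest p; every endothelin system member; at most 4 members of each other list by smallest unadjusted p; and at most 5 leaders per direction of the fit with the replicate number as a block. Genes known only by a clone name were skipped. Other genes named, among them Col1a1, Sparc, Krt14, Krt5, Cd68, Pmp22, Mcam, Myh11 and those in the lists added later, were chosen after their values were seen.

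Other settings were quantile normalization, centring on the median, no filter, a filter at the 75th percentile (a mean signal of 147), 50 added before log2, no intensity trend, no probe sets ending in _x_at or _s_at, each array left out, the replicate number as a block, the same with each number left out, and the mean of probe sets per gene. The split of the arrays by the poly(A) spike-in controls was found in the data and used as a block in settings added afterwards. It was placed at the largest gap between arrays in the mean log2 signal of the Bacillus control probe sets. The labels do not say whether control and Et1 arrays with the same number share a culture, so the main comparison had no block.

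The fits were tested on simulated data built from the real levels and spreads, with 200 of 22519 probe sets changed. For the comparison of Et1 with control, limma called 1 of 50 probe sets planted at a 1.5-fold change, 16 of 50 at 2-fold, 33 of 50 at 4-fold and 42 of 50 at 8-fold, and 4 unchanged ones. For the gene list tests over 11666 genes, camera called 4 of 4 shifted lists and 0 of 21 unshifted ones. The simulated noise was independent between probe sets and the lists were random genes. In the real data the estimated correlation within a list reached values such as 0.54 for the contractile genes. The simulation therefore does not show how often camera at the preset correlation calls lists of genes that vary together. Other splits of the real arrays, given below, were also called for some lists. Array quality was compared by exact two-sided permutation tests of 3 against 3 arrays, whose smallest p is 0.1. Medians of gene groups were compared over 100000 permutations, and intervals of medians came from 10000 resamples of the genes.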

Results

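Messenger RNA was measured in primary dermal fibroblasts, cells grown out of the skin of newborn mouse pups, on Affymetrix Mouse430_2 arrays, which carry 1 or more probe sets per gene. Cultures received either 100 nM synthetic endothelin 1 (Et1), a secreted peptide that acts through G-protein-coupled receptors, or no addition, for 24 hours. There were 3 control arrays and 3 Et1 arrays, which the labels call biological replicates. The 2% trimmed mean of the deposited signals ran from 91.7 on Et1 replicate 1 to 179 on Et1 replicate 3, a range of 1.95 times, and all values below are signals scaled to a common trimmed mean of 139. The number of arrays, 3 per group, limits the precision of every comparison.

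The first comparison asked which transcripts differ between fibroblasts with and without Et1. Among the transcripts that rose in the Et1 cultures were those of Mt2 and Mt1, the zinc- and copper-binding metallothioneins, and of Hmox1, the enzyme that breaks down heme. Signals of Mt2 went from 212 ± 18.3 in control to 1059 ± 14.4 in Et1 arrays (mean ± SD, n = 3), a fold of 5.01. Among those that fell, Ccl2, a chemokine which attracts monocytes, went from 888 ± 127 to 203 ± 11.6 (SD, n = 3), and Cxcl5, which attracts neutrophils, from 489 ± 159 to 48.4 ± 19.7 (SD, n = 3). Aspn and Fmod, small leucine-rich proteoglycans that bind collagen, fell by 2.51 and, in 1 of the probe sets of Fmod, by 2.11 on the log2 scale, and Cemip, which takes part in the breakdown of hyaluronan, fell by 2.33.

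Of 22519 probe sets tested with limma, 78 passed an adjusted p of 0.05, 22 of them higher and 56 lower in Et1 cultures. They named 60 genes, 18 higher and 42 lower, and 6 of the probe sets had no gene symbol here. At an unadjusted p under 0.05 there were 2774 probe sets, 1338 of them higher, where chance alone would give 1126. The log2 fold changes of the 78 calls ranged in size from 0.83 to 3.39, with a median of 1.35. The 3 Et1 signals lay all above or all below the 3 control signals for each of the 78, and for 17.6% of all tested probe sets, where chance gives 10%.

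The 10 genes with the largest rises were Car6, Gtpbp2, Mt2, Prr32, Chchd10, Slc7a3, Gch1, Hmox1, Mt1 and Trib3. Car6, a secreted carbonic anhydrase, rose from 128 ± 52.9 to 656 ± 66.8 (SD, n = 3; log2 fold change 2.46, SE 0.32, limma adjusted p = 0.0304). Slc7a3, a transporter of arginine and lysine, rose from 233 ± 69.6 to 780 ± 88.2, and Gch1, the first enzyme of tetrahydrobiopterin synthesis, from 111 ± 6.38 to 359 ± 38.3 (SD, n = 3). Trib3, a pseudokinase of the stress response, had a log2 fold change of 1.36 and Hmox1 one of 1.64. Gtpbp2 had 3 other tested probe sets, all in the same direction.

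The 10 genes with the largest falls were Cxcl5, Cdc20, Aspn, Fabp4, Ptn, Cemip, Ccl2, Fmod, Il6 and Lrrc17. Il6, an inflammatory cytokine, went from 144 ± 33.2 to 34.9 ± 14.4 (SD, n = 3; log2 fold change -2.10, SE 0.33, limma adjusted p = 0.0485). Fabp4, a fatty acid carrier, fell from 273 ± 27.2 to 49.4 ± 12.8 (SD, n = 3), and Ptn, the growth factor pleiotrophin, by 2.49 on the log2 scale. Cdc20, an activator of the anaphase-promoting complex, fell by 2.52 in 1 probe set and by 1.04 in its brightest one, and 1 of the 2 other tested probe sets of Ptn had the opposite sign. Rgs4, a brake on G-protein signalling, missed the threshold at a log2 fold change of -3.10 (limma adjusted p = 0.0503), with a mean signal of 13.6 in Et1 arrays. With 50 added to each signal that log2 fold change was -1.27 (limma adjusted p = 0.0189). The 1 other tested probe set of Rgs4, which was brighter, had the same sign and did not pass the threshold either.

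**Figure D1:**
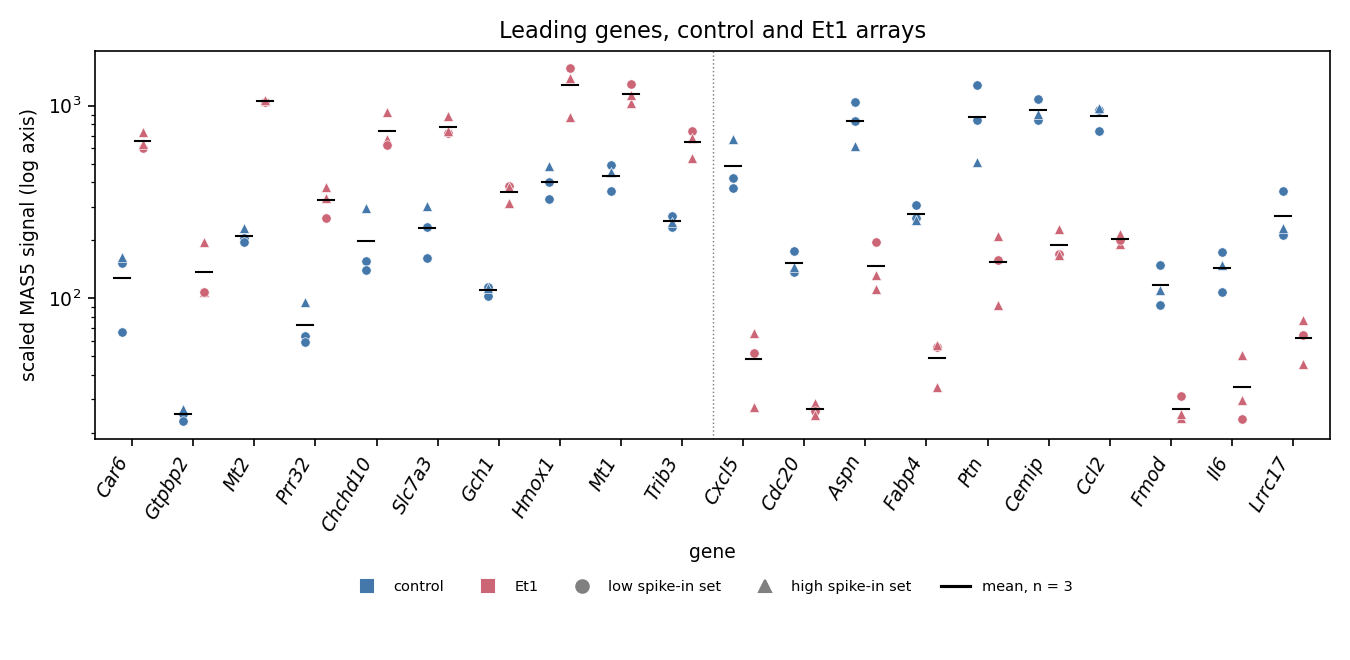
Scaled signal on a log axis for the 10 genes with the largest rises (left of the dotted line) and the 10 with the largest falls (right), 1 point per array, coloured by group, with bars at the means of 3 arrays and the point shape giving the spike-in set. The 3 Et1 points lie on one side of the 3 control points for all 20 genes, as for Ccl2 with means of 888 and 203.

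The arrays also split on a technical measure. Poly(A) spike-in controls are probe sets for bacterial transcripts that can be added to RNA before labelling. Whether they were added here was not established. Their mean log2 signal was 3.52 to 3.82 on control replicates 1 and 2 and Et1 replicate 2, the low set. It was 4.99 to 6.16 on control replicate 3 and Et1 replicates 1 and 3, the high set. These signals were low: the dap 3' probe set, 1 of them, read 49.6 to 63.8 in the low set and 104 to 272 in the high set. With the spike-in set as a block, chosen after seeing the data, limma called 868 probe sets, 312 higher and 556 lower, among them each of the 78. Leaving out an array changed the count to 4 without control replicate 1, 4 without control replicate 2, 229 without control replicate 3, 10 without Et1 replicate 1, 46 without Et1 replicate 2 and 6 without Et1 replicate 3. With 50 added to each signal, the log2 fold changes of Gtpbp2, Cdc20, Fmod and Il6 shrank to 1.29, -1.40, -1.11 and -1.19.

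**Figure D2:**
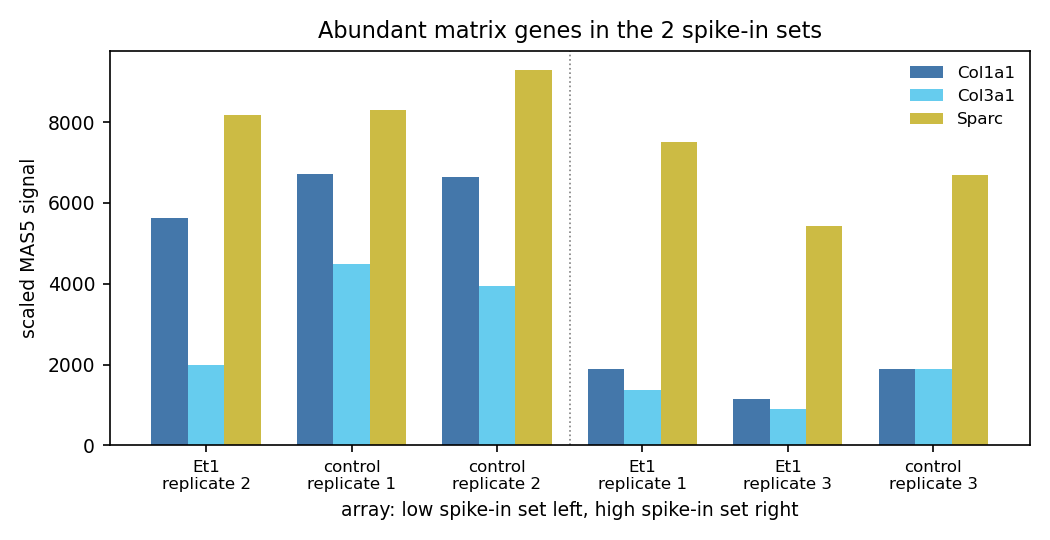
Scaled signals of Col1a1, Col3a1 and Sparc on each array, with the low spike-in set on the left and the high spike-in set on the right. Col1a1 averaged 6331 in the low set and 1646 in the high set.

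The gene lists were fixed before the data were examined and asked whether groups of genes known for their part in fibroblast biology moved together. Lists for mitosis and for the making of cholesterol had lower means in Et1 cultures for all 31 and all 29 tested members, with 1 member of each past the threshold in its brightest probe set. In the list of cytokines and chemokines 18 of 21 had lower means, and in that of the unfolded protein and amino acid stress response 19 of 33 had higher means. Limma's camera test with a preset correlation of 0.01 between genes called 14 of the 27 lists with at least 5 tested members, 1 higher and 13 lower. With an estimated correlation it called 0 of them, and the smallest adjusted p was 0.135.

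Of 21 tested cytokine, chemokine and prostaglandin genes, 4 fell, namely Ccl2, Ccl7, Cxcl5 and Il6, and 0 rose; adjusted over the list alone, 6 fell. The median log2 fold change of the list was -0.36 (-0.18 with no filter), and its camera call (adjusted p = 8.8e-08) was lost at an adjusted p = 0.135 with an estimated correlation. Cxcl1, at -0.63 in its brightest probe set, fell by 1.82 in another. Ccl7, a monocyte chemokine, went from 787 ± 115 to 226 ± 21.1 (SD, n = 3). The list of 17 interferon-stimulated genes was not called (limma camera adjusted p = 0.575), and none of its members passed the threshold. Bst2 had a log2 fold change of -0.81 and Irf9 one of 0.33, which were -0.38 and 0.21 with 50 added to each signal. At an unadjusted p under 0.05, 0 of these 17 were higher and 0 lower.

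All 31 tested genes of the G2 and M phases had lower means in Et1 cultures, with a median log2 fold change of -0.64, and 1 of them, Cdc20, passed over all probe sets in its brightest probe set and Prc1, which bundles spindle microtubules, in another; adjusted over the list alone, 23 fell. The list was called with limma camera at an adjusted p = 1.62e-19, and not with an estimated correlation (adjusted p = 0.138). Ube2c, which works with Cdc20 in mitotic exit, had a log2 fold change of -1.04, and Mki67, a marker of proliferating cells, one of -0.81. The 27 genes of the S phase had a median of 0.16 and were not called (adjusted p = 0.343); Cdt1, which licenses replication origins, stood at 0.59 and Rrm1, a subunit of ribonucleotide reductase, at -0.45. The 26 cyclins, inhibitors and p53 targets were not called (adjusted p = 0.545), with Gadd45a at 1.39 and Gas1 at -2.03.

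All 29 tested genes of cholesterol and fatty acid synthesis had lower means in Et1 cultures, with a median of -0.65. Idi1, which makes the isoprenoid building block dimethylallyl diphosphate, fell from 440 ± 40.2 to 178 ± 27.6 (SD, n = 3) as the 1 member whose brightest probe set passed over all probe sets; adjusted over the list alone, 16 fell. Hmgcs1, which makes HMG-CoA, fell by 1.03 and 1.16 in 2 probe sets that were not its brightest. Scd2, a fatty acid desaturase, had a log2 fold change of -1.28 (limma adjusted p = 0.0546) and Cyp51, a demethylase of lanosterol, one of -1.05. The camera call (adjusted p = 1.26e-16) was lost at an adjusted p = 0.135 with an estimated correlation. The 27 genes of hypoxia and glycolysis had a median of -0.34, with 0 past the threshold over all probe sets and 6 lower and 1 higher adjusted over the list alone. Their camera call (adjusted p = 4.42e-05) was lost at an adjusted p = 0.135 with an estimated correlation; Bnip3, a mitophagy receptor, stood at -0.92 and Ero1a, an oxidase of the endoplasmic reticulum, at 0.80.

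The list of the unfolded protein and amino acid stress response was the 1 called higher, with a median of 0.37 over 33 genes. In it Trib3, Aldh1l2, Vldlr and Nupr1 rose, and adjusted over the list alone 13 rose and 6 fell. Aldh1l2, a mitochondrial enzyme of folate metabolism, went from 592 ± 32.3 to 1209 ± 97.0, and Nupr1, a small stress-induced chromatin protein, from 823 ± 157 to 1914 ± 257 (SD, n = 3). The 6 that fell in the list alone were Creld2, Sdf2l1, Calr, Pdia3, Pdia6 and Hsp90b1, chaperones and folding enzymes of the endoplasmic reticulum, with Calr at -0.99. The camera call (adjusted p = 0.0133) was lost at an adjusted p = 0.135 with an estimated correlation. The correlation estimated for this list was -0.0101, below the preset 0.01, yet its unadjusted camera p rose from 0.00641 to 0.0351. A larger correlation is thus not the cause of that rise, and the cause was not tested. The call was also lost at an adjusted p = 0.0898 without Et1 replicate 2, where the median was 0.19.

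**Figure D3:**
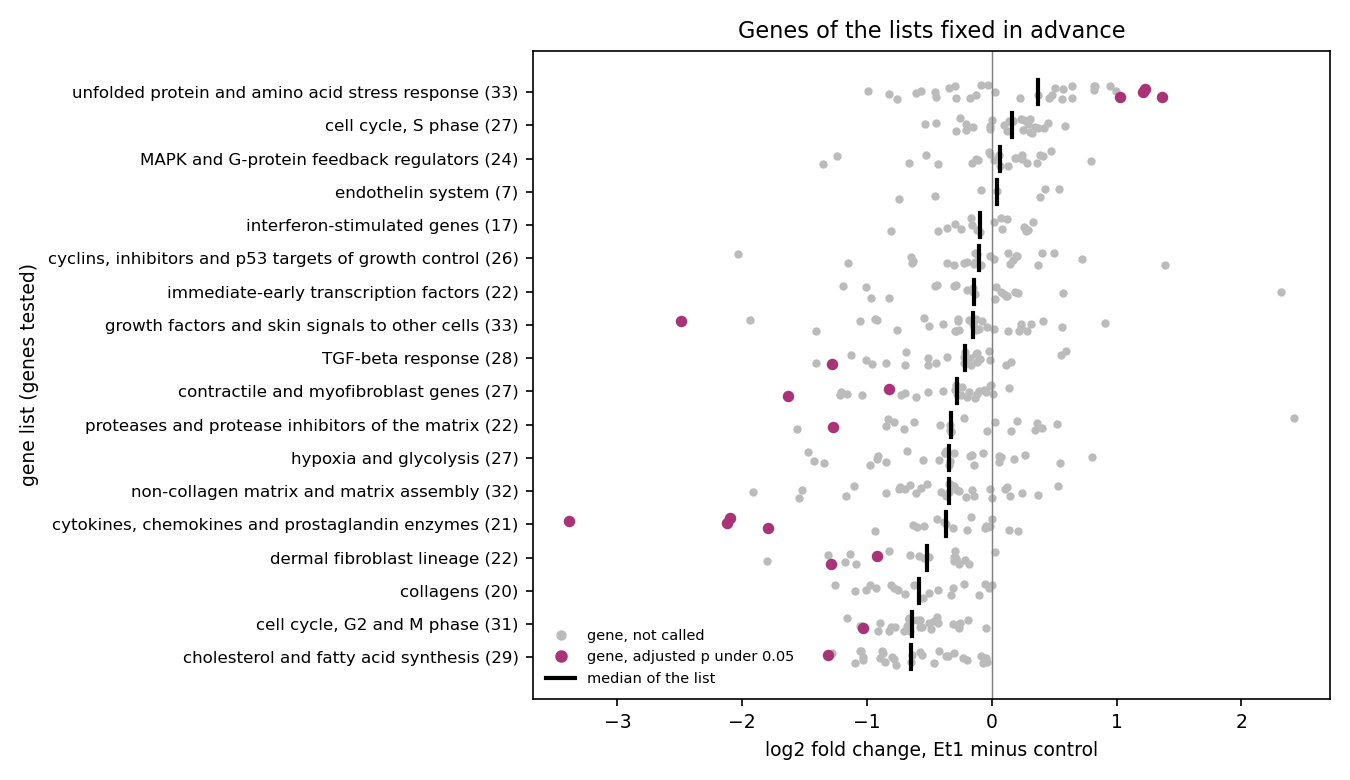
Log2 fold change, Et1 minus control, of each tested gene (points) in the 18 gene lists fixed in advance, with the number of genes tested in brackets, the median of each list (black bar) and genes past the threshold over all probe sets in purple. The medians run from 0.37 for the stress response to -0.65 for cholesterol and fatty acid synthesis.

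Genes of the extracellular matrix and of contraction were lower as lists, and the same lists were also lower in the high spike-in set. All 20 tested collagens had lower means in Et1 cultures, with a median of -0.59, 0 past the threshold over all probe sets and 6 lower adjusted over the list alone (limma camera adjusted p = 1.58e-07, and adjusted p = 0.255 with an estimated correlation). The 3 chains of collagen VI stood at -1.09 for Col6a1, -1.01 for Col6a2 and -0.98 for Col6a3. The 32 other matrix genes had a median of -0.34, with 0 past the threshold in the brightest probe set and 7 lower adjusted over the list alone (camera adjusted p = 3.76e-07, and adjusted p = 0.289 with an estimated correlation); Efemp1, a fibulin, stood at -1.17. Among 27 contractile genes, with a median of -0.28, Mylk, the myosin light chain kinase, fell by 1.63 and Vcl, which links actin to adhesions, by 0.83, and 6 fell adjusted over the list alone. That list's camera call (adjusted p = 1.73e-08) was lost at an adjusted p = 0.289 with an estimated correlation. Of its 27 genes, 25 had lower and 2 higher means in Et1 cultures. Acta2, an abundant member, overlapped between the groups, with signals of 8120 to 8681 in control and 7030 to 11689 in Et1 arrays. Without control replicate 1 the medians were -0.35 for collagens and -0.23 for other matrix genes, and without Et1 replicate 3 they were -0.33 and -0.21, and -0.17 for contractile genes, whose median was -0.45 without Et1 replicate 2.

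Of 28 genes of the response to TGF-beta, with a median of -0.22, Id4 fell by 1.28, and adjusted over the list alone 8 fell and 1 rose (limma camera adjusted p = 2.53e-06, and adjusted p = 0.135 with an estimated correlation). Tgfb2 stood at -1.13 in its brightest probe set and fell by 1.72 in another. Of 22 matrix proteases and inhibitors, with a median of -0.33, Adamts12 fell by 1.28, and adjusted over the list alone 5 fell and 1, Serpinb2, rose (camera adjusted p = 0.00863, and adjusted p = 0.164 with an estimated correlation). Of 33 growth factors and skin signals, with a median of -0.15, Ptn fell, as did Vegfd, a lymphatic growth factor, in 2 probe sets that were not its brightest (by 1.24 and 1.42), and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00824, and adjusted p = 0.135 with an estimated correlation). Among 22 genes of dermal fibroblast lineage, with a median of -0.52, the homeobox genes Prrx1 and Prrx2 fell by 0.92 and 1.29, and 8 fell adjusted over the list alone. The lineage list's camera call (adjusted p = 8.06e-11) was lost at an adjusted p = 0.135 with an estimated correlation; Pdgfrb, a receptor of platelet-derived growth factor, stood at -1.14. Without control replicate 1 the medians of the proteases and the growth factors were -0.21 and -0.10, and without Et1 replicate 2 that of the growth factors was -0.24. With 50 added to the signals the median of the proteases was -0.21.

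The spike-in sets moved with several of these lists. High minus low set, with the group in the fit, the median of the collagens was -0.53 (camera adjusted p = 4.73e-05). It was -0.23 for the other matrix genes (camera adjusted p = 0.00372) and -0.23 for the contractile genes (camera adjusted p = 8.62e-06). With an estimated correlation none of these was called (camera adjusted p = 0.748, 0.802 and 0.748). With the set as a block the median of the collagens was -0.28, against -0.39 within the low set and -0.16 within the high set. For the other matrix genes the block gave -0.26 (-0.33 and -0.17 within the sets), for the contractile genes -0.15 (-0.12 and -0.20), for the TGF-beta response -0.18 (-0.20 and -0.15) and for the lineage genes -0.41 (-0.56 and -0.31). All 14 called lists were also called by camera with the block at the preset correlation; an estimated correlation, run without the block, called 0 (smallest adjusted p = 0.135). With the block, the medians of the G2 and M phase and cholesterol lists were -0.62 and -0.63.

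Lists that follow signalling by receptors such as those for Et1 did not pass. The 22 immediate-early transcription factors had a median of -0.14 (limma camera adjusted p = 0.172), with 0 past the threshold over all probe sets and, adjusted over the list alone, Atf3 and Myc higher and Fos lower. Their medians within the low and high spike-in sets were 0.02 and -0.02. The 24 regulators of MAPK and G-protein feedback had a median of 0.06 (adjusted p = 0.907), a mean of -0.03 and a camera direction below 0; adjusted over the list alone, Dusp4 rose and Spry1 and Grk5 fell.

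The endothelin system was examined because the added peptide is one of its ligands. Of 7 tested members, 0 passed limma's threshold over all probe sets and 0 adjusted over the list alone, and camera did not call the list (adjusted p = 0.907). Ece2 and Ece1, which cut endothelin precursors, had signals of 229 ± 36.1 and 327 ± 118 in control and 332 ± 41.2 and 189 ± 48.0 in Et1 arrays (SD, n = 3; adjusted p = 0.274 and 0.378). Edn1, the gene of the peptide itself, went from 64.3 ± 11.1 to 47.0 ± 9.19, and Ednrb, an endothelin receptor, from 64.4 ± 10.4 to 60.3 ± 6.15 (SD, n = 3). Edn2, Edn3 and Ecel1 had log2 fold changes of 0.39, 0.42 and 0.04. Mme and Kel lay below the filter, with highest signals of 27.2 and 43.2. Ednra, the other endothelin receptor, was not analysed here.

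Of the marker lists of other cell types in skin, 2 were called, both lower. The pericyte and smooth muscle list had a median of -0.64 over 6 genes (limma camera adjusted p = 0.00137, and adjusted p = 0.289 with an estimated correlation), with 0 past the threshold and 3 lower adjusted over the list alone, Cnn1, Mcam and Myh11, of which Cnn1 and Myh11 also stand in the contractile list. Within the low and high spike-in sets that median was -0.85 and -0.17, and it was -0.39 with 50 added to the signals and -0.41 with no filter. The Schwann cell list had a median of -0.45 over 7 genes (camera adjusted p = 0.023, and adjusted p = 0.164 with an estimated correlation). In it 1 member passed the threshold, Pmp22, a myelin protein also made by fibroblasts. The median of the Schwann cell list was -0.25 with 50 added to the signals and -0.26 with no filter. That list was not called by camera without control replicate 1, control replicate 3, Et1 replicate 2 or Et1 replicate 3, at adjusted p = 0.056, 0.0569, 0.0606 and 0.0533 and medians of -0.28, -0.30, -0.51 and -0.21. The adipocyte list, with Fabp4 as its 1 called member of 5, had a median of -0.07 and was not called by camera with all arrays (adjusted p = 0.0604, and adjusted p = 0.236 with an estimated correlation). It was called lower with all arrays by fry (adjusted p = 0.0141), by camera with the spike-in set as a block (adjusted p = 0.0334, median -0.34) and with the mean of probe sets per gene (adjusted p = 0.0157), and by camera without control replicate 1, control replicate 2 or Et1 replicate 1, at adjusted p = 0.0259, 0.0413 and 0.0417. Its medians were -0.19, -0.24 and -0.41 without control replicates 1, 2 and 3, and -0.26, -0.24 and -0.13 without Et1 replicates 1, 2 and 3.

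The lists of keratinocyte, melanocyte, endothelial, macrophage, skeletal muscle, and chondrocyte and bone markers were not called, with camera adjusted p of 0.907, 0.907, 0.687, 0.907, 0.907 and 0.854, and had 0 members past the threshold. Krt14 and Krt5, keratins of the basal epidermis, had mean signals of 110 and 137 in control arrays, and Cd68, a macrophage protein, 43.4. Median and camera direction differed in sign for keratinocyte and melanocyte markers, and median and mean for endothelial and skeletal muscle markers. The mast cell list had 3 tested members, too few for a list test, and 0 passed.

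RNA quality was read from the ratio of 3' to 5' control probe sets of housekeeping genes. For Gapdh the ratio was 0.746 ± 0.0253 in control and 0.724 ± 0.0417 in Et1 arrays (SD, n = 3; two-sided exact permutation p = 0.6). For beta-actin it was 1.19 ± 0.00924 and 1.18 ± 0.0439 (SD, n = 3; exact permutation p = 0.9), where 3 against 3 cannot go below 0.1. For the transferrin receptor, added after seeing the data, it was 2.81 ± 0.252 and 3.07 ± 0.83 (SD, n = 3; exact permutation p = 0.7), with 3.86 on Et1 replicate 1 and 2.20 on Et1 replicate 3. Signals of the 18S ribosomal RNA probe set followed the spike-in sets, at 4.83 to 19.7 in the low set and 85.4 to 149 in the high set.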

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

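The settings with the spike-in set as a block were chosen after seeing the data; all others were planned. Against 78 probe sets called with limma, the count was 567 with the replicate block (170 higher, 397 lower), 40 with no filter, 7 with no intensity trend, 868 with the spike-in set as a block and 934 with that block and quantile normalization; leaving out arrays or replicate numbers gave 4 to 2818. Each of the 78 was called under the replicate block, 4, 4, 73, 9, 41 and 6 of them were called without control replicates 1, 2 and 3 and Et1 replicates 1, 2 and 3, and all 40 of the no-filter calls were among the 78. Quantile normalization, median centring, the 75th percentile filter, 50 added to the signals and leaving out _x_at and _s_at probe sets gave 64 to 113. The fit without an intensity trend and the fits with 1 array fewer changed the variance estimate or its degrees of freedom by construction; beyond that the cause was not tested.

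The replicate numbers were checked for pairing, since the series describes cells divided between a control and a treated culture without saying which arrays share one. Deviations from the group means correlated at -0.12, 0.44 and 0.45 across probe sets for arrays numbered 1, 2 and 3. Et1 replicate 1 correlated best with control replicate 3 (0.26), so not every array correlated best with its own number. The arrays numbered 2 share the low spike-in set, those numbered 3 share the high set, and those numbered 1 lie in different sets. Control replicate 3 and Et1 replicate 1 are both in the high set. The check therefore cannot tell pairing from the spike-in sets. With the replicate block 13 lists were called in place of 14, without the Schwann cell list (adjusted p = 0.0677).

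Camera with an estimated correlation called 0 lists, with the medians as before: -0.59 for collagens, -0.34 for other matrix genes, -0.28 for contractile genes, -0.22 for the TGF-beta response, -0.33 for proteases, -0.36 for cytokines, -0.15 for growth factors, -0.64 for the G2 and M phases, -0.65 for cholesterol synthesis, 0.37 for the stress response, -0.34 for hypoxia and -0.52 for the lineage. Fry did not call collagens, other matrix genes or contractile genes at medians of -0.59, -0.34 and -0.28 (adjusted p = 0.167, 0.167 and 0.148), nor the pericyte list (adjusted p = 0.167), and it called the adipocyte list lower (adjusted p = 0.0141), 11 lists in all, 10 of them among the 14. The interferon list was called with no filter at a median of -0.17 (adjusted p = 0.0429), and growth factors were not called under the 75th percentile filter at -0.15 (adjusted p = 0.0729). Over the settings that left out arrays or numbers, the median of the stress list ran from 0.19 to 0.42, that of the immediate-early list from -0.24 to 0.00329 and that of the S phase list from 0.0579 to 0.27. With the replicate block the immediate-early list was called lower without number 2 (adjusted p = 0.00748) and without number 3 (adjusted p = 0.0318), the S phase list higher without number 3 (adjusted p = 0.0184), and the stress list was not called without number 2 (adjusted p = 0.116). With that block and without number 1 the medians of the proteases and the growth factors were -0.17 and -0.0253, and both lists were called. For these the cause was not tested. The estimated correlation was below the preset 0.01 for the growth factors (-0.00397), the stress response (-0.0101) and the Schwann cell list (-0.00495). Their unadjusted camera p rose all the same, so the loss of these calls does not show that their genes vary together.

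Of the endothelin genes 0 were called under each setting except the replicate block without number 1, which called 2; leaving out arrays or numbers gave 0 to 2. All 32 named probe sets past the threshold kept their sign under every setting that tested them. Their groups do not overlap, which fixes the sign in the settings that left out or blocked arrays. The ratio of 3' to middle control probe sets differed between the groups by 0.00761 for Gapdh (exact permutation p = 0.7) and by -0.0152 for beta-actin (exact permutation p = 0.6). A block of array batch from the experiment files was not run, because their settings were identical for the 6 arrays.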

Other observations

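All lists in the opening paragraphs were written after the results had been seen, as were all tests below except those of the dim array, the count of lists over splits, the group label and the level-matched lists. Genes that make and import amino acids were higher in Et1 cultures: of 22 tested, 21 had higher means, with a median log2 fold change of 0.61, 2 passed over all probe sets (Slc7a3 and Aldh1l2), and 15 rose adjusted over the list alone. Since genes past the threshold prompted the list, it was also run without them and without its members in other lists: 11 of the 12 tested genes left had higher means, with a median of 0.52 (adjusted p = 0.0186 with an estimated correlation over the 3 lists run this way, and 0.0132 for the full list over 7). Psph and Phgdh, enzymes of serine synthesis, stood at 1.08 and 0.56, Cth, which makes cysteine, at 1.04, and Asns, asparagine synthetase, at 0.83 (limma adjusted p = 0.0503). The cytosolic aminoacyl-tRNA synthetases had a median of 0.42, with 17 of 19 higher; Wars, which loads tryptophan, rose by 1.15, and 9 rose adjusted over the list alone (adjusted p = 0.0984 with an estimated correlation over 7 lists). Without Wars the median was 0.40, and the adjusted p of 0.0421 with an estimated correlation was lower because it was taken over 3 lists. Of these 23 and 20 genes, 9 and 0 also stood in lists fixed in advance.

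Chaperones and folding enzymes of the endoplasmic reticulum were lower, with 16 of 18 below control, a median of -0.44, and 8 lower and 1 higher (Dnajb9) adjusted over the list alone; 11 of its genes stood in lists fixed in advance. Without those, 6 of the 7 tested genes left had lower means, with a median of -0.36 (adjusted p = 0.0393 with an estimated correlation over the same 3 lists, and 0.0132 for the full list over 7) and 0 past the threshold adjusted over the list alone. P4hb, protein disulfide isomerase, stood at -0.51 and Hsp90b1 at -0.46. Medians within the low and high spike-in sets were 0.74 and 0.56 for amino acid genes, 0.50 and 0.28 for cytosolic synthetases and -0.45 and -0.38 for the chaperones. Among 13 cytosolic heat shock proteins the median was -0.07 and the list was not called (adjusted p = 0.155), although Hspa1b fell by 1.07 and 1.22 in 2 probe sets that were not its brightest.

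A hypothesis from these values is a response shared by genes that the transcription factor ATF4 is known to drive, which include cytosolic but not, as a class, mitochondrial synthetases. The cytosolic median exceeded the mitochondrial one by 0.22 (0.42 against 0.20; permutation p = 0.0204 across genes, which are not independent replicates). With the spike-in set as a block the difference was 0.11 (0.35 against 0.24; permutation p = 0.244), so this hypothesis was left undecided. Atf4 itself stood at 0.51 (limma adjusted p = 0.161). A second hypothesis, a response shared by targets of NRF2, was also left undecided: without Hmox1 and Sqstm1 the remaining 19 target genes had a median of 0.16 (adjusted p = 0.472 with an estimated correlation), and with them 21 genes had a median of 0.17 (adjusted p = 0.278 with an estimated correlation).

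The first pattern weighed is the 78 probe sets called between Et1 and control. All 78 were called with the spike-in set as a block. They were picked by the fit without it, and their groups do not overlap. Their calls with the block were thus nearly fixed and cannot weigh the unequal numbers of arrays of each set. Without the dim array Et1 replicate 1 the median ratio of their log2 fold changes to those with it was 0.998 (lowest 0.873). Calls made with that array need Et1 values close together, so a ratio near 1 was largely built in and decides nothing about that array. Without it 9 of the 78 were still called. The 6 arrays make 10 splits, too few for a share under 0.05; 2 of the 10, the real one included, called as many, and the highest other was 2749, for the split that follows the spike-in sets, which points to a structure of the arrays. For the 14 of 27 lists called, 1 of the 10 splits reached the count and the highest other was 12, again too few to decide. Each other split called lists at the preset correlation, from 1 to 12 of them. All but the spike-in split did so with 0 probe sets called, so a list call at that setting is not particular to Et1. An effect of Et1 on the cultures stays among the open explanations.

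The second pattern is the difference between the spike-in sets, in which 3760 probe sets differed with the group in the fit, 16.7% of those tested, among them Col1a1, the main chain of collagen I, with signals of 6331 ± 606 in the low set and 1646 ± 422 in the high set (SD, n = 3), a log2 difference of -1.87. RNA degradation in one set is argued against by 3' to 5' ratios of Gapdh and beta-actin that differed by at most 1.04 times between the sets, while that of the transferrin receptor was 3.02 ± 0.108 in the low set and 2.86 ± 0.878 in the high set (SD, n = 3). Dilution by other cells stays open. The 20 brightest collagen, matrix and lineage genes had a median of -0.37 (95% interval over genes -0.49 to -0.23), the direction dilution gives, although less than the -1.87 of Col1a1. Col3a1, Col1a2, Sparc and Acta2, all abundant, stood at -0.99, -0.50, -0.37 and -0.05. Of 9 marker lists of other cells 0 were called higher and 1 lower in the high set. Et1 replicate 1 lay on the Et1 side of control replicate 3 for 95.5% of 673 probe sets with an unadjusted limma p under 0.01 between the other arrays. Control replicate 3 was among the arrays that picked these probe sets, which favours that side. The share that a wrong group label on Et1 replicate 1 would give was not computed, so that explanation was left undecided. A difference in labelling, in background or in the cultures also stays open, and none of them was tested.

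The third pattern is the lower G2 and M phase list beside an S phase list that was not lower. With the spike-in set as a block the median of the G2 and M phase list was -0.62, against -0.64 without it, so the sets do not account for it. Of 10000 random lists matched on level, 0 had a median as low (lowest -0.29), which speaks only to a fall shared by genes of that level. The random lists were drawn gene by gene, whereas the estimated correlation within this list was 0.40. Their count therefore does not measure chance, and camera with an estimated correlation did not call the list (adjusted p = 0.138). A smaller share of dividing cells of every phase, as the whole cause, is argued against in these arrays by the S phase median of 0.16. Its 95% interval over genes, from -0.02 to 0.29, lies far above the G2 and M phase median. With the block the S phase median was 0.08 (-0.06 to 0.19). Genes are not independent replicates, so these intervals do not measure the spread between cultures. The bound of that test was set after these values were seen. At an unadjusted limma p under 0.05, 1 S phase gene was higher (Cdt1) and 2 were lower (Rrm1 at -0.45 and Tk1 at -0.54). The median therefore does not speak for every member of that list. The S phase list was itself higher in the high set by camera (adjusted p = 0.0344, and adjusted p = 0.802 with an estimated correlation). Whether cells paused or skipped a phase was not measured.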
